A study of Mus musculus with 35 samples.

How the data were processed

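Messenger RNA of sorted hind paw skin cells was sequenced as stranded TruSeq libraries with single-end reads of 50 bases, per the labels' protocols. Reads were demultiplexed with bcl2fastq, aligned with TopHat2 to the mouse build mm9 and counted per gene with HTSeq, per the submitters' processing notes; tool versions, annotation and strand setting are not given in the sources used here. The deposited values are whole-number read counts per gene symbol, 1 table per library, with no normalization. The 35 tables share 22609 symbols, of which 17169 had a count in at least 1 library. HTSeq's lines for reads outside genes or without a unique place were left out of library sizes and tests. Over the 9 groups, on average 12.1 to 25.5% of reads lay in no gene, 35.9 to 55.3% had no unique place and 21.2 to 49.3% were counted in genes. Reads without a unique place are not counted, so levels of genes with near-identical copies (Hspa1a and Hspa1b) are uncertain. Those of related genes (Tpsab1 and Tpsb2, Mrgprb1 and Mrgprb2) may be uncertain too. No coordinates are given, because the reference used here was of another build than mm9.

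Groups were taken from the labels: 3 populations, each with vehicle females, vehicle males and PTX males. Each population was fitted apart in R 4.3.3 with edgeR 4.0.16: filterByExpr, TMM scaling, glmQLFit with robust estimation and 1 coefficient per group, and the two-sided quasi-likelihood F-test with Benjamini-Hochberg adjustment at 0.05. PTX males were compared with vehicle males and vehicle females with vehicle males, and PTX effects were compared between populations with an interaction term in a fit over both. CPM values are scaled with TMM within the population, or over the libraries of both for differences between populations and over all libraries for the population markers, so the same gene has slightly different levels in these parts. Gene lists of cell types and pathways (53 lists, with 943 of 955 entries found) were tested where at least 5 genes were tested, with camera of limma 3.58.1 (preset correlation 0.01), with an estimated correlation and with fry. List levels are means of log2(CPM + 1). A gene with no count in a group is given as a bound from a floor of 3 counts per library. Intervals and floors cover counting error only.

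The comparisons, lists, alternatives and naming rule were fixed before the data were examined. Named genes were, for each PTX comparison and direction, the 10 with the largest log2 fold change among those that passed, with a mean of at least 5 CPM in the higher group and no overlap between groups; 5 per direction were named for the other comparisons, without the overlap criterion for differences between populations. Clone-like and predicted symbols were passed over. Where none passed, the 3 with the lowest p were taken; that sex-linked and passed-over symbols do not count there was settled after values were seen. For each list up to 4 passing members with the lowest p could be named, or at most 2 others as values.

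The alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, only the 2 groups compared, limma with voom quality weights, vehicle males and females together as controls, plain CPM for markers, a threshold of 0.01 for overlaps, and leaving out each library of the groups compared. PTX males against vehicle females, only genes most abundant in the own population, overlaps in opposite directions and the fit without the keratinocyte library with the fewest counts were added after seeing the data. No pair of libraries agreed within counting noise.

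The tests were tested on simulated data with 200 changed genes per population. For immune cells (11766 genes) the edgeR test recovered 0% of 2-fold, 7.69% of 4-fold, 15.8% of 8-fold, 42.5% of 32-fold and 48.7% of 128-fold changes, with 0 of 11536 unchanged genes called. For fibroblasts (10657 genes) it recovered 0%, 0%, 10.3%, 7.69% and 25.6%, and for keratinocytes (10649 genes) 0%, 0%, 2.5%, 10% and 15.8%, with 1 of 10453 unchanged genes called. DESeq2 called 93, 110 and 251 unchanged genes in these 3 simulations. The biological coefficient of variation was 1.23 in immune cells, 1.41 in fibroblasts and 1.71 in keratinocytes, so changes of a few fold were seldom detectable.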

Results

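Messenger RNA was sequenced from 35 libraries of cells sorted from mouse hind paw skin, in 3 populations. Immune cells were sorted by CD45 from wild-type mice, fibroblasts by tdTomato under an inducible Col1a2 Cre, and keratinocytes by tdTomato under an inducible K5 Cre. Each population came from vehicle-treated females, vehicle-treated males and males given paclitaxel (PTX), a chemotherapy drug that stabilises microtubules. PTX was given as 2 intraperitoneal doses of 2 mg/kg a day apart, and skin was taken 6 days after the last dose. Each of the 9 groups held 4 libraries, except the keratinocytes of vehicle males with 3. Counts in genes ranged from 13847475 to 18979776 per immune library, from 13359088 to 20809036 per fibroblast library and from 6518070 to 12055718 per keratinocyte library. Replicate 2 of the vehicle female keratinocytes had 988712. The labels do not say that each library came from a separate mouse, so p-values measure only the spread between these samples, which may be technical.

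The vehicle libraries carried the markers of their sort. Ptprc, which encodes CD45, was at 588 ± 125 CPM (gene counts scaled to library size, mean ± SD, n = 4 unless stated) in immune libraries of vehicle females and at 472 ± 94.2 in those of vehicle males. Col1a2, a fibrillar collagen gene, was at 9460 ± 359 and 10770 ± 2521 CPM in the fibroblast libraries, and the basal keratin gene Krt5 at 5064 ± 1614 and 5548 ± 1345 CPM (n = 3) in the keratinocyte libraries. Markers of other cell types differed between groups of the same sort. In immune libraries Col1a2 was at 18.6 ± 17.8 CPM in vehicle females, 794 ± 332 in vehicle males and 167 ± 106 in PTX males, and the endothelial gene Pecam1 at 40.7 ± 21.9, 85.1 ± 80.4 and 0.164 ± 0.144. In keratinocyte libraries Col1a2 was at 11.8 ± 9.90, 1.10 ± 0.234 (n = 3) and 1988 ± 754 CPM in the same order, and Ptprc at 1.64 ± 0.907, 0.484 ± 0.116 (n = 3) and 154.5 ± 31.98. Krt5 was at 1893 ± 1033 CPM in the keratinocytes of PTX males. In fibroblast libraries the group means of Ptprc lay between 0.759 and 3.08 CPM and those of Krt5 between 0.158 and 0.543 CPM.

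**Figure D1:**
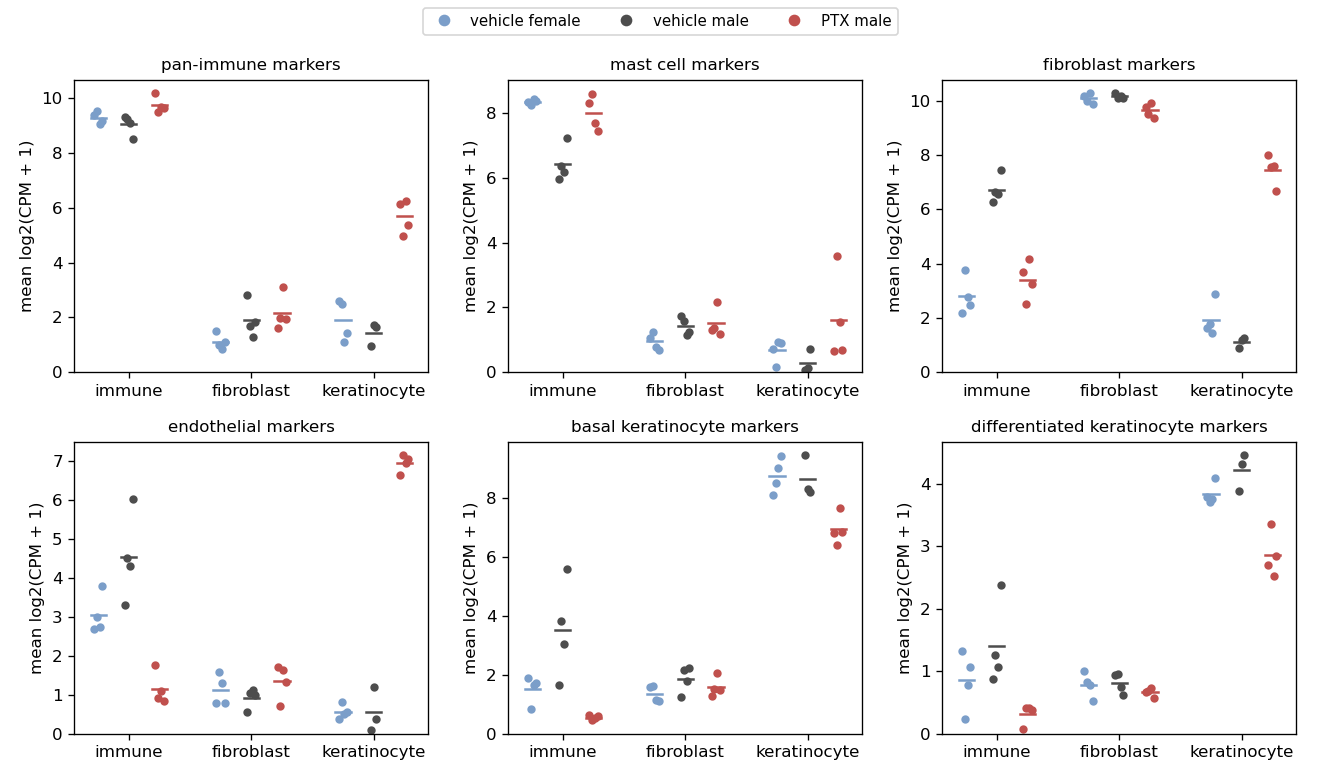
Mean log2(CPM + 1) of 6 marker lists per library (points, lines for group means) in the 3 sorted populations, by vehicle female, vehicle male and PTX male. The fibroblast list averaged 6.73 in the immune libraries of vehicle males against 2.79 in vehicle females and 3.41 in PTX males, and 7.47 in the keratinocyte libraries of PTX males against 1.11 in vehicle males.

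The first comparison asked which transcripts of skin immune cells differed 6 days after PTX, in males. Against vehicle males, the immune libraries of PTX males held more RNA of chemokine, stress-response, MHC class II and mast cell genes. They held less RNA of matrix, vessel, muscle and keratinocyte genes. Against vehicle females, a comparison chosen after seeing the data, the list medians were -0.09 for mast cell and 0.38 for collagen and matrix genes. The mast cell rise and the matrix fall thus did not hold against both vehicle groups. Ccl4, a chemokine that attracts monocytes and T cells, rose from 135 ± 53.02 to 1289 ± 229.8 CPM (log2 fold change 3.26 ± 0.32 SE, n = 4 and 4, adjusted p = 0.000732). Tnfaip3, which encodes the NF-kB inhibitor A20, rose from 634.5 ± 90.6 to 1976 ± 360.4 CPM (1.64 ± 0.18, adjusted p = 0.000748). Dcn, a proteoglycan gene of fibroblasts, fell from 2501 ± 956.5 to 177 ± 179.9 CPM (-3.82 ± 0.66, adjusted p = 0.0079). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 116 of 12131 tested genes higher and 553 lower, and 2435 genes had an unadjusted p under 0.05. The 2 groups did not overlap for 1683 genes (13.9%), against 2.86% by chance for 4 against 4. Of the genes called lower, 289 (52.3%) were most abundant in the vehicle libraries of fibroblasts and 145 (26.2%) in those of keratinocytes, against 31.5% and 38.2% of all tested genes. Of the genes called higher, 89 of 116 (76.7%) were most abundant in the vehicle libraries of immune cells, against 30.3% of all tested genes.

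Among the gene lists with higher values, 7 of 34 cytokine and chemokine genes rose and 3 fell (9 and 6 adjusted over the list alone, list median 0.75 on the log2 scale, camera adjusted p = 2e-05). With an estimated correlation the list had adjusted p = 0.0543. Ccl3, a chemokine gene, rose from 139 ± 31.2 to 557 ± 61.2 CPM (2.00 ± 0.24, adjusted p = 0.00121), Cxcl16 by 1.43 ± 0.24 and Cxcl2 by 1.47 ± 0.26. The inflammatory cytokine genes Tnf and Il1b, named after their values were seen, rose by 1.75 ± 0.34 and 1.75 ± 0.35. The 3 that fell, also named after their values were seen, were Cxcl14, Tgfb3 and Cxcl12, which stromal cells express (Tgfb3 had adjusted p = 0.089 without vehicle male 3, and lost its call in 6 of the 8 fits with 1 library left out). Of 15 genes of the NF-kB feedback list, which holds subunit genes such as Rel beside inhibitors, 4 rose (7 adjusted over the list alone, median 0.88, adjusted p = 9.33e-09). The NF-kB list had adjusted p = 0.0543 with an estimated correlation, and Nfkbia rose by 0.99 ± 0.17 beside Tnfaip3. Of 21 immediate early genes, 4 rose (6 adjusted over the list alone, median 0.45, adjusted p = 4.72e-07). The immediate early list had adjusted p = 0.0703 with an estimated correlation. Nr4a1, an orphan nuclear receptor gene, went from 2378 ± 132 to 5313 ± 527 CPM. Of 14 heat shock genes, 5 rose and 2 fell (7 and 2 adjusted over the list alone, median 0.91, adjusted p = 8.06e-06). The heat shock list had adjusted p = 0.0939 with an estimated correlation. Hspa1a, an inducible Hsp70 gene with a near-identical copy in Hspa1b, rose from 1277 ± 103 to 4199 ± 1228 CPM (1.72 ± 0.21, adjusted p = 0.00175). The small heat shock genes Cryab and Hspb8 fell (Hspb8 had adjusted p = 0.059 without vehicle male 4, and lost its call in 3 of 8 such fits). In the same libraries the pan-immune markers averaged 9.06 log2(CPM + 1) in vehicle males and 9.77 with PTX, and the fibroblast markers 6.73 and 3.41. In plain CPM these levels were 9.23 and 9.48 for the pan-immune markers, and 6.9 and 3.2 for the fibroblast markers.

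Antigen-presenting and mast cell genes were also higher with PTX. Of 14 dendritic and Langerhans cell genes, 5 rose (6 adjusted over the list alone, median 1.60, adjusted p = 2.87e-09). The dendritic cell list had adjusted p = 0.0702 with an estimated correlation. The genes included the MHC class II genes H2-Ab1 (3778 ± 706 to 11930 ± 4679 CPM, 1.66 ± 0.27, adjusted p = 0.00661), H2-Eb1 and H2-Aa, and the invariant chain gene Cd74 at 1.40 ± 0.24. Of 15 macrophage genes, 2 rose (3 adjusted over the list alone, median 0.59, adjusted p = 1.86e-05). The macrophage list had adjusted p = 0.143 with an estimated correlation. Its level went from 9.57 to 9.95 log2(CPM + 1), but from 9.74 to 9.68 in plain CPM. Cd14, a co-receptor for endotoxin, was at 4550 ± 629 against 1767 ± 371 CPM. Of 12 mast cell genes, 9 rose (10 adjusted over the list alone, median 1.77, adjusted p = 3.21e-15). The mast cell list had adjusted p = 0.0543 with an estimated correlation. The tryptase gene Tpsab1, related to Tpsb2, rose from 155 ± 31.9 to 652 ± 138 CPM (2.07 ± 0.24, adjusted p = 0.000964). The chymase gene Mcpt4 rose by 1.64 ± 0.28 and the stem cell factor receptor gene Kit by 1.92 ± 0.35. For PTX males minus vehicle females, a comparison chosen after seeing the data, the mast cell list had a median of -0.09 (adjusted p = 0.828). Against vehicle females the dendritic cell list kept a median of 1.25 (adjusted p = 8.95e-07, and adjusted p = 0.135 with an estimated correlation) and the cytokine list 0.42 (adjusted p = 0.000959, and adjusted p = 0.135 with an estimated correlation), while the macrophage list was at 0.09 (adjusted p = 0.197) and the type I interferon list at 0.53 (adjusted p = 0.106). The mast cell list averaged 8.36 ± 0.0806 log2(CPM + 1) in vehicle females, 6.44 ± 0.552 in vehicle males and 8.02 ± 0.527 in PTX males.

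**Figure D2:**
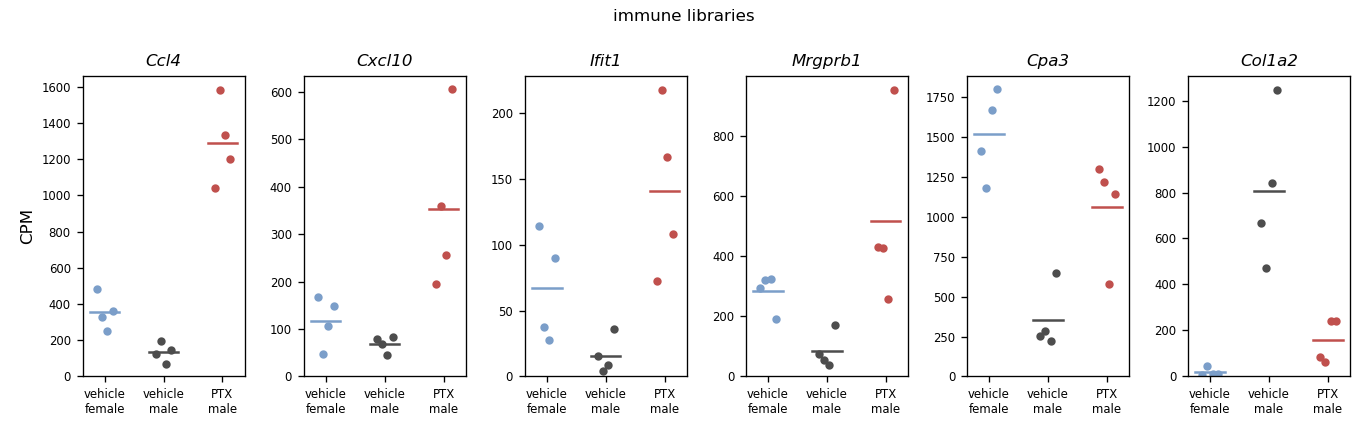
CPM of Ccl4, Cxcl10, Ifit1, Mrgprb1, Cpa3 and Col1a2 in each immune library (points, lines for group means) of vehicle females, vehicle males and PTX males. Ccl4 averaged 1289 CPM with PTX against 135 in vehicle males, while Col1a2 and Cpa3 differed between the vehicle groups as well.

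The 10 genes with the largest rises under the fixed rule were Oasl1, Ccl4, Ifit1, Smad4, Ifih1, Mrgprb1, Cxcr6, Mrgprb2, Pik3r6 and Cxcl10. By that rule each was higher in every PTX library than in every vehicle male library. Oasl1, Ifit1, Ifih1 and Cxcl10 belong to the type I interferon list. Of its 24 genes 4 rose and Ifit3 fell (5 and 1 adjusted over the list alone, median 1.06, adjusted p = 0.00078, and adjusted p = 0.082 with an estimated correlation). Cxcl10, a ligand of CXCR3, was at 354 ± 181 against 69.0 ± 17.2 CPM (2.36 ± 0.45, adjusted p = 0.0125) and Ifit1 at 141 ± 64.0 against 15.9 ± 14.2 (3.15 ± 0.76, adjusted p = 0.0312). Ifit3 was at 0.0193 ± 0.0387 against 11.6 ± 7.05 CPM (adjusted p = 0.0231, and 0.0556 without vehicle male 3). Mrgprb1 and Mrgprb2, related receptor genes of which the second is a mast cell receptor for basic peptides and drugs, were at 517 ± 302 against 84.4 ± 59.7 CPM and at 119.8 ± 51.9 against 20.1 ± 16.4 CPM. Beside these rises, the fibroblast gene Col1a2 was at 157 ± 97.2 CPM with PTX against 806 ± 329.6 in vehicle males. Ccl4 stayed past the threshold without any single library of the groups compared, and the other 9 did not. Adjusted p was 0.0995 for Oasl1, 0.0911 for Ifih1, 0.053 for Mrgprb1, 0.101 for Cxcr6, 0.105 for Mrgprb2 and 0.118 for Pik3r6 without vehicle male 2. It was 0.0989 for Ifit1 and 0.0525 for Cxcl10 without vehicle male 3, and 0.115 for Smad4 without PTX male 4. Of the 8 fits with 1 library left out, 6 lost the call of Pik3r6, 5 those of Oasl1, Smad4, Ifih1 and Cxcr6, 4 those of Ifit1 and Mrgprb2, 2 that of Cxcl10 and 1 that of Mrgprb1.

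The genes lower with PTX included 13 of 29 fibrillar collagen and matrix genes (21 adjusted over the list alone, median -3.77, adjusted p = 3.31e-13, and adjusted p = 0.0543 with an estimated correlation). Of 15 fibroblast markers, 7 fell (11 adjusted over the list alone, median -3.01, adjusted p = 9.33e-09, and adjusted p = 0.0717 with an estimated correlation). Dpt fell from 159 ± 51.0 to 1.79 ± 1.001 CPM (-6.47 ± 0.98, adjusted p = 0.00588) and Col5a2 from 151 ± 78.2 to 1.72 ± 0.894 (-6.45 ± 0.95, adjusted p = 0.00563). Vehicle females were low in these genes too. For PTX males minus vehicle females the fibroblast list was higher (median 0.82, adjusted p = 0.00123, and adjusted p = 0.338 with an estimated correlation), as was the collagen and matrix list (0.38, adjusted p = 0.0132, and adjusted p = 0.347 with an estimated correlation). Of 20 basement membrane and hemidesmosome genes, 7 fell (11 adjusted over the list alone, median -4.34, adjusted p = 2e-05). The basement membrane list had adjusted p = 0.117 with an estimated correlation. The laminin gene Lamb2 fell from 225 ± 68.8 to 1.92 ± 0.714 CPM (-6.87 ± 0.68, adjusted p = 0.000732). Of 25 matrix protease genes 2 fell (7 adjusted over the list alone, median -2.67, adjusted p = 0.0026). The protease list had adjusted p = 0.082 with an estimated correlation, and Mmp2 was at -5.34 ± 0.69. Of 13 endothelial markers 6 fell (9 adjusted over the list alone, median -9.02, or -6.31 with genes at 0 set to their bound, adjusted p = 3.37e-07, and adjusted p = 0.0702 with an estimated correlation). Of 11 pericyte and smooth muscle markers 5 fell (9 adjusted over the list alone, median -6.49, adjusted p = 5.67e-08, and adjusted p = 0.073 with an estimated correlation). Pecam1 was at 0.160 ± 0.142 against 86.2 ± 80.4 CPM and the pericyte gene Rgs5 at 0.504 ± 0.336 against 136 ± 141 CPM. Against vehicle females the endothelial list kept a median of -3.92 (adjusted p = 1.09e-05) and the pericyte list -4.13 (adjusted p = 5.27e-06), each with adjusted p = 0.135 with an estimated correlation.

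Smaller lists of other tissues moved the same way in the immune libraries. Of 11 basal keratinocyte markers 4 fell (9 adjusted over the list alone, median -9.09, or -6.00 at bounds, adjusted p = 0.000327). The basal keratinocyte list had adjusted p = 0.14 with an estimated correlation, and Krt5 was at 0.208 ± 0.0528 against 187 ± 270.2 CPM. Of 9 skeletal muscle markers 3 fell (6 adjusted over the list alone, median -10.24, or -5.68 at bounds, adjusted p = 0.000158, and adjusted p = 0.121 with an estimated correlation). Against vehicle females these 2 lists had medians of -2.46 (adjusted p = 0.197) and -1.92 (adjusted p = 0.363). Of 22 mitosis genes 3 fell (7 adjusted over the list alone, median -5.22, or -4.01 at bounds, adjusted p = 0.000858, and adjusted p = 0.082 with an estimated correlation). Kif20a and Aurkb, a motor and a kinase of cell division, were at 0 in all 4 PTX libraries against 6.47 ± 4.45 and 7.32 ± 4.18 CPM, with adjusted p = 0.0525 and 0.0656 without vehicle male 2 (1 and 3 of 8 such fits lost the call). Against vehicle females the mitosis list had a median of -3.47 (adjusted p = 2.95e-05, and adjusted p = 0.123 with an estimated correlation). Beside these falls, the PTX libraries had 5956 to 8700 genes over 10 counts against 11000 to 12813 in vehicle males, and correlated among themselves at 0.3235 to 0.5594 (Spearman) against 0.7595 to 0.8921. Low correlations were not particular to these libraries. They ran from 0.2547 to 0.5197 in PTX fibroblasts and from 0.333 to 0.6831 in vehicle male fibroblasts. In keratinocytes they ran from 0.2296 to 0.4482 with PTX and from 0.1873 to 0.4264 in vehicle males. The 10 largest falls under the rule in immune libraries were Selp, Asb5, Tnnc2, Mast4, Sh2d3c, Mettl13, Arl16, Nos3, Hey1 and Kdr. Selp, Nos3 and Kdr are endothelial genes and Tnnc2 is a muscle gene. Selp was at 0 with PTX against 45.2 ± 52.1 CPM, at least 197-fold lower with a floor of 3 counts per library, and Nos3 at least 66.1-fold lower. Tnnc2 was lower by a ratio of 3780 (95% counting interval 678 to 149000, from 1 count). Adjusted p was 0.0644 for Selp without vehicle male 2, 0.0792 for Mettl13, 0.0569 for Arl16 and 0.0879 for Hey1 without vehicle male 3, and 0.0786 for Kdr without vehicle male 4. Hey1 lost its call in all 8 such fits, Kdr in 7, Mettl13 in 6, Selp in 3 and Arl16 in 2. The tubulin and microtubule list had a median of 0.24 over 18 genes (camera adjusted p = 0.364).

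The immune count rested on the vehicle males: 230, 232 and 279 genes were called without vehicle male 2, 3 and 4, against 669 with all libraries. With voom quality weights 37 genes were called higher and 1 lower, and each of the 10 named falls lost its call in at least 1 alternative. With an estimated correlation camera called 0 of the 48 lists (lowest adjusted p = 0.0543) against 32 with the preset one, and fry called 28.

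The same question in fibroblasts gave far fewer calls. Igfbp3, which encodes a binding protein of insulin-like growth factors, rose with PTX from 110.5 ± 31.95 to 836 ± 265 CPM (2.92 ± 0.40, n = 4 and 4, adjusted p = 0.00782). Col3a1, a fibrillar collagen gene, fell from 13660 ± 4102 to 4456 ± 1870 CPM (-1.62 ± 0.26, adjusted p = 0.0359). These were the 2 genes the edgeR test called among 10857, and each PTX library lay beyond every vehicle male library for both. At an unadjusted p under 0.05 there were 876 genes, and the groups did not overlap for 347 (3.2%, against 2.86% by chance). Col1a2 and Col1a1 were at 3881 ± 1405 against 9007 ± 2320 CPM (-1.21 ± 0.24, adjusted p = 0.106) and at 3799 ± 1717 against 9096 ± 3036 CPM (-1.26 ± 0.28, adjusted p = 0.228). The collagen and matrix list was lower (1 of 30 genes, or 5 adjusted over the list alone, median -0.32, adjusted p = 0.0389). So was the fibroblast list (1 of 15 genes, or 3 adjusted over the list alone, median -0.31, adjusted p = 0.0394). The pericyte list (11 genes, median 1.44, adjusted p = 0.00757), heat shock list (14 genes, median 0.60, adjusted p = 0.00757), oxidative stress list (21 genes, median 0.52, adjusted p = 0.0339) and NF-kB feedback list (13 genes, median 0.63, adjusted p = 0.0394) were higher. Each of the 6 lists had adjusted p = 0.659 with an estimated correlation. Rgs5, a pericyte gene, was at 671 ± 872 against 68.4 ± 8.35 CPM (3.29 ± 0.75, adjusted p = 0.228). Hsp90ab1 was at 3361 ± 1462 against 2062 ± 312 CPM (0.70 ± 0.26, adjusted p = 0.469) and Sod2, which encodes mitochondrial superoxide dismutase, at 475 ± 147.8 against 197 ± 58.5 CPM (1.27 ± 0.38, adjusted p = 0.468). The tubulin list had a median of -0.43 (16 genes, adjusted p = 0.815).

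The PTX fibroblast libraries had more reads without a unique place, 42.2 ± 4.69% against 35.9 ± 0.881% (exact permutation p = 0.0286, two-sided, the smallest possible for 4 against 4, 0.103 adjusted over 18 such tests). Col3a1 lost its call in 6 of the 8 fits with 1 library left out (adjusted p = 0.228 without PTX male 2) and Igfbp3 in 2 (adjusted p = 0.0623 without vehicle male 3). The edgeR test called 0 genes without vehicle male 1 or 3, 1 without vehicle male 2, PTX male 3 or PTX male 4, 3 without vehicle male 4 and 4 without PTX male 1. With RLE scaling, which moved the median log2 fold change of all genes from 0.076 to 0.235, Igfbp3 was the 1 gene called and the 2 lower lists were not called.

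**Figure D3:**
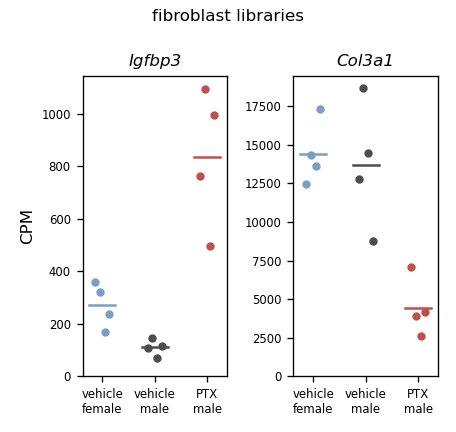
CPM of Igfbp3 and Col3a1 in each fibroblast library (points, lines for group means) of vehicle females, vehicle males and PTX males. Igfbp3 averaged 836 CPM with PTX against 110.5 in vehicle males, and Col3a1 4456 against 13660.

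In keratinocytes, genes of the epidermis fell with PTX and genes of other skin cells rose. Krt10, the keratin of differentiating keratinocytes, fell from 1473 ± 445 (n = 3) to 126 ± 56.8 CPM (n = 4, -3.55 ± 0.42, adjusted p = 0.000118). Perp, a p53 target needed for desmosomes, fell from 5052 ± 612 to 906 ± 259 CPM (-2.48 ± 0.25, adjusted p = 1.27e-05), and the basal keratin gene Krt15 from 1951 ± 122 to 358 ± 88.5 CPM (-2.45 ± 0.35, adjusted p = 0.000664). Col1a2 rose from 1.35 ± 0.257 to 2580 ± 1006 CPM (10.89 ± 0.81, adjusted p = 1.6e-07). The edgeR quasi-likelihood test called 126 of 10939 genes higher and 33 lower, 1619 had an unadjusted p under 0.05, and the groups did not overlap for 1470 genes (13.4%, against 5.71% by chance for 4 against 3). Of the 126 genes called higher, 70 (55.6%) were most abundant in the vehicle libraries of fibroblasts and 55 (43.7%) in those of immune cells, while all 33 called lower were most abundant in those of keratinocytes.

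Of 10 differentiated keratinocyte genes 3 fell (6 adjusted over the list alone, median -2.09, adjusted p = 9.11e-09, and 0.00803 with an estimated correlation). They were Krt10, Krt1 and Krtdap, a secreted peptide gene of differentiating keratinocytes that went from 1790 ± 94.2 to 273 ± 165 CPM. Of 14 basal keratinocyte genes 4 fell (7 adjusted over the list alone, median -1.83, adjusted p = 9.12e-08, and 0.0337 with an estimated correlation). Krt14 went from 13460 ± 1521 to 3527 ± 2089 CPM (-1.93 ± 0.32, adjusted p = 0.00314), beside Krt15, Krt5 and Col17a1. Without PTX male 2 Krt5 had adjusted p = 0.0965, without vehicle male 1 Col17a1 had 0.12, and without vehicle male 3 Krt1 had 0.1. The call was lost in 5, 4 and 2 of 8 such fits. The 10 largest falls under the rule were Fgfbp3, Capns2, Cst6, Defb6, Gnai1, Krt10, Them5, Fam25c, Aqp3 and Krtdap, each of which the rule required to be lower in every PTX library than in every vehicle male library. Aqp3, the water and glycerol channel of the basal epidermis, fell from 1088 ± 409 to 161 ± 66.6 CPM (-2.76 ± 0.47, adjusted p = 0.00296) and Fam25c by 2.81 ± 0.50 on the log2 scale. Krt10, Fam25c, Aqp3 and Krtdap passed in each fit with 1 library left out. For the others adjusted p was 0.196 for Fgfbp3, 0.278 for Capns2 and 0.146 for Defb6 without vehicle male 2, 0.0859 for Cst6 without PTX male 2, 0.151 for Gnai1 without vehicle male 1 and 0.165 for Them5 without vehicle male 3. Gnai1 lost its call in all 8 such fits, Them5 in 6, Fgfbp3, Capns2 and Cst6 in 5 and Defb6 in 1. Ribosomal protein genes (44 genes, 1 lower and 3 adjusted over the list alone, median -0.65, adjusted p = 0.000146) and oxidative phosphorylation genes (35 genes, 1 lower and 1 adjusted over the list alone, median -0.65, adjusted p = 0.000232) were lower as lists. They had adjusted p = 0.342 and adjusted p = 0.0825 with an estimated correlation. In these libraries the pan-immune markers averaged 5.69 log2(CPM + 1) with PTX against 1.44 in vehicle males, and the fibroblast markers 7.47 against 1.11.

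Among the genes that rose were 7 of 14 fibroblast markers (13 adjusted over the list alone, median 10.91, or 10.52 at bounds, adjusted p = 4.95e-20, and 0.000942 with an estimated correlation). Of 13 endothelial markers 9 rose (11 adjusted over the list alone, median 11.18, or 10.75 at bounds, adjusted p = 1.68e-19, and 0.000571 with an estimated correlation), and of 29 collagen and matrix genes 9 rose (18 adjusted over the list alone, median 8.75, adjusted p = 5.45e-18, and 0.00351 with an estimated correlation). Esam, an endothelial junction gene, went from 0.272 ± 0.242 to 519.6 ± 199 CPM (10.75 ± 1.52, adjusted p = 0.000625). Of 14 macrophage genes 3 rose (10 adjusted over the list alone, median 6.55, adjusted p = 6.14e-11, and 0.0204 with an estimated correlation). The lysozyme gene Lyz2 went from 22.6 ± 6.07 to 1001 ± 395 CPM (5.47 ± 0.77, adjusted p = 0.000625). Of 5 dendritic cell genes 4 rose (4 adjusted over the list alone, median 6.19, adjusted p = 4.75e-05, and adjusted p = 0.0573 with an estimated correlation), Cd74 among them at 6.39 ± 0.94. Of 27 cytokine genes 5 rose (11 higher and 1 lower adjusted over the list alone, median 6.12, adjusted p = 4.52e-11, and 0.00257 with an estimated correlation). Il6 went from 0.423 ± 0.116 to 858 ± 677 CPM (10.93 ± 1.35, adjusted p = 0.000164), and Ccl2 rose by 10.12 ± 1.60, beside Ccl7, Cxcl12 and Csf3. Adjusted p was 0.0743 for Ccl7 without PTX male 2 and 0.0882 for Cxcl12 without vehicle male 2, and each lost its call in 3 of 8 such fits. Of 16 complement genes 3 rose (10 adjusted over the list alone, median 6.77, adjusted p = 2.19e-10, and 0.00486 with an estimated correlation), led by Serping1, the C1 inhibitor gene, at 2012 ± 554 against 1.17 ± 0.392 CPM. Of 21 immediate early genes 4 rose (13 adjusted over the list alone, median 2.34, adjusted p = 1.41e-07, and 0.0337 with an estimated correlation), and Fos was at 3830 ± 1093 against 539 ± 413 CPM (2.83 ± 0.51, adjusted p = 0.0047). These groups moved with the fibroblast, endothelial and pan-immune markers of the same libraries, which included Ptprc at 201 ± 44.5 against 0.598 ± 0.169 CPM (8.35 ± 2.05, adjusted p = 0.0481, lost in all 8 such fits, with 0.237 without vehicle male 3).

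The 10 largest rises under the rule were Tnfaip6, Scara5, Csf3, Tek, Rce1, Has1, Cldn5, Fabp4, Gpr116 and Sele, several of them endothelial (Tek, Cldn5, Sele, Gpr116) or stromal genes. Scara5 was at 209 ± 164 CPM with PTX and at 0 in the 3 vehicle male libraries, at least 644-fold higher, and Tnfaip6, a hyaluronan-binding protein gene, was at least 680-fold higher. Has1, a hyaluronan synthase gene, was at 332 ± 177 CPM, a ratio of 8620 (counting interval 1550 to 340000), Sele at 566 ± 191 CPM, a ratio of 5180 (1770 to 25100), and the fatty acid binding protein gene Fabp4 at 552 ± 194 CPM, a ratio of 7310 (2020 to 60300). Rce1, Has1, Fabp4 and Sele passed in each fit with 1 library left out. Adjusted p was 0.124 for Tnfaip6, 0.13 for Csf3 and 0.202 for Tek without vehicle male 3, and 0.0976 for Scara5, 0.0704 for Cldn5 and 0.0522 for Gpr116 without PTX male 2. Tek lost its call in all 8 such fits, Csf3 in 6, Scara5 in 4, Tnfaip6 in 3 of the 5 that tested it, Gpr116 in 2 and Cldn5 in 1. Rce1 was also at 148 ± 81.4 CPM in vehicle females. The vehicle male libraries held Pecam1 at 107 ± 185 CPM (n = 3), with 319.9 in the highest.

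**Figure D4:**
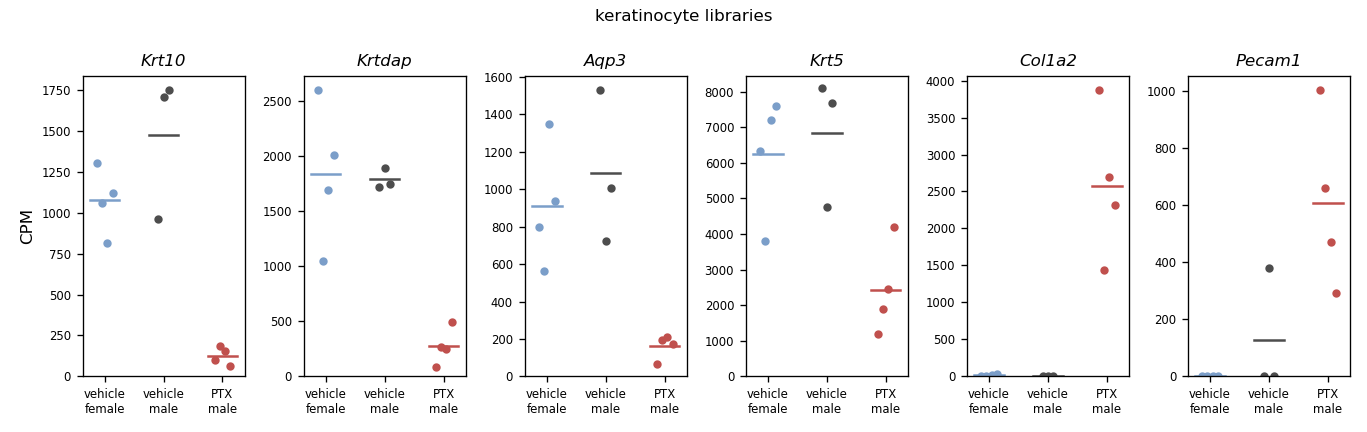
CPM of Krt10, Krtdap, Aqp3, Krt5, Col1a2 and Pecam1 in each keratinocyte library (points, lines for group means) of vehicle females, vehicle males and PTX males. Krt10 averaged 126 CPM with PTX against 1473 in vehicle males, and Col1a2 2580 against 1.35.

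The neutrophil list did not move with the other immune markers in these libraries (8 genes, median 0.61, adjusted p = 0.942), nor did the mitosis list (22 genes, median -0.29, adjusted p = 0.251), the tubulin list (15 genes, median -0.49, adjusted p = 0.458) or the wound keratin and alarmin list (9 genes, median -1.20, adjusted p = 0.11) pass the test. The keratinocyte count rested on single libraries as well: 84 genes were called without vehicle male 3, 87 without PTX male 2, 100 without PTX male 3 and 94 without PTX male 4, against 159 with all.

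Whether the PTX effect itself differed between populations was asked with an interaction term, over genes tested in both populations and with CPM scaled over both. Markers of other cells differed between groups of the same sort. In these differences the content of the sorts cannot be told apart from a PTX effect on the cells. Endothelial genes moved in opposite directions in immune and keratinocyte libraries. Selp, which encodes P-selectin of activated endothelium and platelets, was at 0 with PTX against 56.6 ± 66.5 CPM in the immune libraries, and at 630 ± 224 against 0.136 ± 0.127 CPM (n = 3) in the keratinocyte libraries (adjusted p = 1.22e-05). Cldn5, a tight junction gene of endothelium, was at 0.0615 ± 0.0766 against 79.8 ± 49.3 CPM and at 253 ± 133 against 0.0259 ± 0.0448 CPM (adjusted p = 1.03e-05), and Icam2 differed in the same way (adjusted p = 0.000279), as did Ecscr and Myct1. The edgeR test called 22 genes with a higher PTX effect in immune cells and 914 with a higher one in keratinocytes among 10109. The fibroblast list (12 of 14 genes lower in the immune minus keratinocyte difference, 13 adjusted over the list alone, camera adjusted p = 2.69e-21, and 0.000194 with an estimated correlation), the endothelial list (12 of 13 genes, 12 adjusted over the list alone, adjusted p = 1.21e-15, and 0.000664 with an estimated correlation) and the macrophage list (12 of 14 genes, 13 adjusted over the list alone, adjusted p = 2.16e-17, and 0.000814 with an estimated correlation) were lower in this difference. Ccdc138, Mcm8, Fgfbp3, Uba6 and Wdr67 were the 5 named in the other direction. Without 1 library adjusted p was 0.266 for Ccdc138 without immune PTX male 2, 0.0844 for Mcm8 and 0.979 for Fgfbp3 without immune PTX male 1, 0.262 for Uba6 without keratinocyte vehicle male 1 and 0.141 for Wdr67 without immune PTX male 3. Of 15 such fits, 11 lost the call of Ccdc138, 9 those of Mcm8, Fgfbp3 and Wdr67, and 1 that of Uba6.

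Between immune cells and fibroblasts 41 of 10113 genes had a higher PTX effect in immune cells and 340 a higher one in fibroblasts. The adhesion genes Mcam and Esam were lower with PTX in immune libraries (0.0756 ± 0.103 against 65.2 ± 45.9 CPM for Mcam) and did not pass in fibroblast libraries (27.6 ± 36.0 against 0.0213 ± 0.0425 CPM, adjusted p = 0.228, and 0.468 for Esam). The interaction had adjusted p = 0.00033 for Mcam and 0.00122 for Esam. The collagen and matrix list differed (14 of 29 genes lower, 18 adjusted over the list alone, median -3.46, adjusted p = 1.68e-17, and 0.0013 with an estimated correlation), and the immediate early list was higher in immune cells (1 of 21 genes, 3 adjusted over the list alone, median 0.48, adjusted p = 0.00117, and adjusted p = 0.191 with an estimated correlation). Between fibroblasts and keratinocytes 17 of 9534 genes had a higher effect in fibroblasts and 391 a higher one in keratinocytes. Mc5r, a melanocortin receptor gene of sebaceous glands, was at 71.6 ± 55.2 against 0.0199 ± 0.0399 CPM in fibroblast libraries and at 36.3 ± 42.4 against 196 ± 118 CPM (n = 3) in keratinocyte libraries (adjusted p = 0.00801). The cytokine list was lower in this difference (8 of 24 genes, 12 adjusted over the list alone, median -5.94, adjusted p = 3.97e-11, and 3.81e-05 with an estimated correlation). It moved with the macrophage list (median -5.93, adjusted p = 1.32e-07, and 0.0239 with an estimated correlation) and the pan-immune list (median -5.26, adjusted p = 0.000544, and adjusted p = 0.105 with an estimated correlation), whose level in the keratinocyte libraries was 5.69 with PTX against 1.44 in vehicle males.

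Immune cells and keratinocytes shared 10 genes called higher with PTX, against 1.25 expected for independent lists among 10109 genes (Fisher's exact test, p = 4.24e-07): B2m, Ccl7, Cd74, Fth1, H2-Aa, H2-Ab1, H2-Eb1, Jun, Nfkbia and Zfp36. At a threshold of 0.01 they shared 2, Cd74 and H2-Ab1. With 1 library left out, 5 of 8 immune fits lost the call of B2m, 7 that of Zfp36, 2 that of Fth1 and 1 that of Jun. Of 8 keratinocyte fits, 7 lost that of Nfkbia, 6 that of Fth1, 5 those of H2-Aa and Jun, 4 that of H2-Eb1 and 3 those of Ccl7 and Zfp36. Beside these rises, the pan-immune markers of the keratinocyte libraries averaged 5.69 log2(CPM + 1) with PTX against 1.44 in vehicle males. Immune cells and keratinocytes shared 5 called lower, against 1.28 expected (Fisher's exact test, p = 0.00815): Col17a1, Krt14, Krt5, Krtdap and Trim29, of which Col17a1 and Krt14 lost their immune call in 7 and 6 of 8 such fits. In opposite directions, an overlap examined after seeing the data, 42 genes were lower in immune cells and higher in keratinocytes, against 5.57 expected (Fisher's exact test, p = 3.38e-26). Fisher's test treats genes as independent, which they are not, since markers of the same cell type can move together. The p-values of these overlaps therefore do not measure evidence for a shared response to PTX.

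The last comparison set vehicle females against vehicle males. In immune libraries mast cell protease genes were higher in females and genes of stroma lower. PTX males differed from the same vehicle male libraries in the same directions. The mast cell list averaged 8.36 log2(CPM + 1) in females, 6.44 in vehicle males and 8.02 in PTX males, and the fibroblast list 2.79, 6.73 and 3.41. A trait of these vehicle male sorts thus cannot be told apart from a difference between the sexes. Tpsab1 was at 589.5 ± 93.4 CPM in females and 155 ± 31.9 in males (1.92 ± 0.23, n = 4 and 4, adjusted p = 0.00186), Mcpt4 at 1258 ± 243 and 305 ± 105 (2.04 ± 0.28, adjusted p = 0.00639), and Cpa3, Tpsb2 and Cma1 were also called higher. Cfd, the adipocyte gene of complement factor D, was at 0.242 ± 0.114 against 644 ± 734 CPM (adjusted p = 4e-04), and Cyp2e1, C1qtnf3, Wisp2 and Ptgis were called lower. The edgeR test called 8 of 12131 genes higher and 35 lower, with 499 at an unadjusted p under 0.05 and 847 (6.98%) not overlapping. Of 12 mast cell genes 6 were higher (10 adjusted over the list alone, median 1.91, adjusted p = 4.22e-35, and 0.00245 with an estimated correlation), and 6 of 29 collagen and matrix genes were lower (21 adjusted over the list alone, median -4.21, adjusted p = 1.22e-55, and 0.000981 with an estimated correlation), beside 6 of 15 fibroblast markers (11 adjusted over the list alone, median -4.42, adjusted p = 5.38e-42, and 0.00245 with an estimated correlation). Adjusted p was 0.136 for Cpa3, 0.142 for Tpsb2 and 0.142 for Cma1 without vehicle male 2, and 0.202 for Cyp2e1, 0.216 for C1qtnf3, 0.0874 for Wisp2 and 0.16 for Ptgis without vehicle female 1. C1qtnf3 and Ptgis lost their calls in all 8 such fits, Cyp2e1 and Wisp2 in 7, and Cpa3, Tpsb2 and Cma1 in 6. The test called 12 genes without vehicle female 1, 15 without vehicle female 3, 14 without vehicle female 4, 20, 16, 15 and 25 without vehicle male 1, 2, 3 and 4, against 43 with all.

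Xist followed the labels in all 3 populations, and the Y-linked genes passed in part. Xist, the X-inactivation transcript, was at 384.5 ± 65.6 CPM in immune libraries of females against 0.476 ± 0.201 in males (adjusted p = 5e-07), at 491 ± 156 against 1.20 ± 0.599 in fibroblasts (adjusted p = 0.000188) and at 2253 ± 345 against 0.660 ± 0.0898 (n = 3) in keratinocytes (adjusted p = 7.16e-09). The Y-linked Eif2s3y was lower in females in immune cells (adjusted p = 0.000118) and fibroblasts (adjusted p = 0.0468, and 0.38 without vehicle female 3, lost in 7 of 8 such fits), and Ddx3y in immune cells (adjusted p = 4e-04). Kdm5d and Uty had adjusted p = 0.0666 and 0.141 in immune cells. In keratinocytes Eif2s3y had adjusted p = 0.229, and Ddx3y overlapped, from 0.304 CPM in the lowest male to 1.099 in the highest female library (adjusted p = 0.591). Xist and Eif2s3y were the 2 genes called of 10857 in fibroblasts, where 298 had an unadjusted p under 0.05, and Xist the 1 gene called of 10939 in keratinocytes, where 877 did. In fibroblasts the immediate early list was lower in females (21 genes, median -0.41, adjusted p = 6.51e-05, and adjusted p = 0.464 with an estimated correlation), as was the pan-immune list (10 genes, median -1.29, adjusted p = 0.00554, and adjusted p = 0.705 with an estimated correlation). In keratinocytes the fibroblast list was higher (14 genes, 0 by the edgeR test and 5 adjusted over the list alone, median 2.39, or 1.80 at bounds, adjusted p = 0.0364, and adjusted p = 0.703 with an estimated correlation). Of genes that did not pass, Col1a2 was at 14.7 ± 11.99 against 1.35 ± 0.257 CPM in keratinocytes (adjusted p = 0.0611), and the adhesion gene Mcam at 50.5 ± 31.0 against 0.0191 ± 0.0382 CPM in fibroblasts (adjusted p = 0.502).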

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

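Of the tests below, those of fibroblast RNA, of vessel RNA, of muscle and keratinocyte RNA, of dilution, of a mixed-up library, of purer sorts, of handling stress and of other splits were chosen only after the result was seen; the test of genes detected was written before.

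In immune libraries genes of other skin cells were lower in PTX males than in vehicle males, and fibroblast RNA carried over in the vehicle male sorts may account for the fibroblast part: 271 fibroblast-restricted genes had a median log2 fold of -3.49 in vehicle females minus vehicle males (quartiles -4.89 and -1.94), and of -0.10 in PTX males minus vehicle females. Carry-over in the vehicle male sorts alone is argued against for 24 endothelial and pericyte genes, which were lower with PTX than in vehicle females too (median -4.03, quartiles -5.70 and -2.52, with list levels at most 1.91 and 1.10 in PTX and at least 2.86 and 2.93 in female libraries), though the lists passed only with the preset correlation (adjusted p = 1.09e-05 and 5.27e-06, against 0.135). For 20 muscle and basal keratinocyte genes it stays open, since they had a median of -3.78 in vehicle females minus vehicle males and of -2.19 in PTX males minus vehicle females (quartiles -3.73 and -0.09), where neither list passed (adjusted p = 0.363 and 0.197). Fewer genes were detected with PTX (10408 ± 659 against 13158 ± 733), and low immune-restricted genes of 2 to 20 CPM had a median of -0.31 (quartiles -4.01 and 1.12), near the -0.78 of other low genes and close to the bound of that test, so a loss of low transcripts remains open. The labels give no sort date or library batch to test, and an effect of PTX on the cells captured was not tested and stays open.

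In keratinocyte libraries, genes of other skin cells were higher with PTX. Other skin cells in the PTX sorts are a candidate source: 49 of the 50 most abundant fibroblast-restricted genes were over 2-fold higher, at a median of 19.9% of their level in fibroblast libraries (quartiles 13.9 and 28.7). The 100 most abundant keratinocyte-restricted genes had a median of -1.86 (quartiles -2.41 and -1.25), near the -2.10 of the differentiated keratinocyte list, close to the bound of that test. Krt10 at -3.55 lay below the lower quartile, but a gene picked for its large fall cannot decide against dilution. The lists of other types moved apart (endothelial 11.18, pan-immune 5.77, neutrophil 0.61). They started from unlike levels in vehicle males (1.44 for pan-immune, 2.28 for neutrophil markers), so their unequal folds do not decide either. A single mixed-up library is excluded, since 4 PTX libraries held more Col1a2 than every vehicle one (lowest 1440 CPM, highest vehicle 31.8). A change of the keratinocytes themselves was not tested and stays open.

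In immune libraries, chemokine, interferon, NF-kB and stress genes were higher with PTX. Purer sorts stay open: 949 immune-restricted genes had a median of 0.49 (quartiles -1.09 and 1.28), within the quartiles of all 108 tested members of these 5 lists, called or not (median 0.86, quartiles 0.20 and 1.42). Against vehicle females these members had a median of 0.60, beside 0.30 for the pan-immune list. Medians were 0.80 for heat shock, 0.78 for NF-kB, 0.59 for immediate early, 0.53 for interferon and 0.42 for cytokine genes. Camera called all but the interferon list with the preset correlation, and none with an estimated one (lowest adjusted p = 0.123). The female sorts held less fibroblast but more endothelial RNA than the PTX ones, so these values do not settle purity. Handling stress of the sorted cells cannot be told apart from a PTX effect: the immediate early list had an adjusted p of 0.0703 with an estimated correlation, and the labels give no handling times to test.

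Relabelling the libraries gave these counts, with the real value, then the highest other split. For genes, 1 of 35 splits reached the real count in immune cells (669, 0), fibroblasts (2, 1) and keratinocytes (159, 6). For females against males 1 of 35 did in immune cells (43, 1) and fibroblasts (2, 0). A share of 1 in 35 is the smallest these splits can give, and it was not adjusted over the tests. For the larger counts (669, 159 and 43) it argues against chance without excluding it. The PTX count in fibroblasts rested on 2 genes, and was 0 to 4 with 1 library left out. Relabelling cannot tell PTX from a difference of sort or batch. For females against males the 2 fibroblast genes were Xist and Eif2s3y, both sex-linked, so that count says nothing of other differences between the sexes. For females against males in keratinocytes 13 of 35 splits did (1, 2), so chance cannot be excluded for a count of 1. The gene itself was Xist (adjusted p = 7.16e-09), called in all 3 populations. For differences between populations 1 of 100 splits did for immune minus fibroblast (381, 16), 1 of 100 for immune minus keratinocyte (936, 507) and 3 of 100 for fibroblast minus keratinocyte (408, 432). These shares lie under 0.05, not adjusted over the 3 differences. For fibroblast minus keratinocyte a relabelled split called more genes than the real labels, so chance is not excluded there. Relabelled splits could also call many genes for immune minus keratinocyte. For lists 1 of 35 splits did in immune cells (32, 23), while 4 of 35 in fibroblasts (6, 8) and 2 of 35 in keratinocytes (26, 26) did, which does not exclude chance.

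Single libraries far from the others of their group, which chance gives in about 1 in 20 groups, numbered 10, with 6.4 expected. The share of reads in genes was 38.7% in immune vehicle female 2 (nearest 44.74) and 50.57% in fibroblast vehicle male 3 (47.92). Col1a2 was at 45.24 CPM in immune vehicle female 2 (11.61), Krt5 at 584.4 in immune vehicle male 4 (111) and at 0.7202 in fibroblast vehicle male 1 (0.1765), and Mrgprb2 at 44.68 in immune vehicle male 4 (12.85). Tnnc2 and Sh2d3c were at 0.08127 CPM in immune PTX male 1 and at 0 in the others, Hey1 at 0.05611 in immune vehicle male 2 (19.37), and Fgfbp3 at 0.1293 in keratinocyte PTX male 2 with the others at 0. The share of reads without a unique place averaged 42.2% in PTX fibroblasts, above the highest control library at 36.96%.

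By the interaction term of the edgeR test, the change with PTX differed between immune and fibroblast libraries for 381 genes, between immune and keratinocyte libraries for 936 and between fibroblast and keratinocyte libraries for 408. Markers of other cells differed between groups of the same sort. These counts cannot tell a PTX effect on the cells from a difference in what the sorts held. For immune minus fibroblast the adjusted p was 0.0192 for Taf1b, 0.0335 for Fam136a, 0.035 for Mrps31, 0.0475 for Klhl36, 0.0447 for Ercc4, 0.00033 for Mcam, 0.0047 for Ddit4l, 0.0272 for Azi1, 0.0126 for Tcfap2c and 0.00122 for Esam. For immune minus keratinocyte it was 0.0383 for Ccdc138, 0.03 for Mcm8, 0.0383 for Fgfbp3, 0.0175 for Uba6, 0.0304 for Wdr67, 1.22e-05 for Selp, 0.00206 for Ecscr, 1.03e-05 for Cldn5, 0.00397 for Myct1 and 0.000279 for Icam2. For fibroblast minus keratinocyte it was 0.0319 for Chac2, 0.0481 for Fgfbp3, 0.048 for Gas2l3, 0.00801 for Mc5r, 0.0319 for Mapk13, 0.0299 for Kcnn3, 0.0106 for Scarf1, 0.033 for Glis1, 0.0401 for Klhl36 and 0.0369 for Dok4. With 1 library left out, the named genes that fell short had these highest values. Taf1b reached 0.0683 and Klhl36 0.169 (fibroblast vehicle male 4), Fam136a 0.0881 and Ercc4 0.0978 (immune vehicle male 4), Mrps31 0.084 (immune vehicle male 3) and Azi1 0.084 (fibroblast PTX male 1). In the last difference Chac2 reached 0.0985 (fibroblast PTX male 1), Fgfbp3 0.124, Gas2l3 0.12 and Scarf1 0.0566 (keratinocyte vehicle male 2), Mapk13 0.0751 (keratinocyte PTX male 2), and Kcnn3 0.0996, Glis1 0.111, Klhl36 0.12 and Dok4 0.115 (keratinocyte vehicle male 3).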

How the results depend on the processing

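The tests against vehicle females, on genes most abundant in the own population and without the keratinocyte library of fewest counts were chosen only after the result was seen. Over the alternatives other than PTX males against vehicle females and genes of the own population, called lists stayed past the threshold in 2160 cases and fell short in 278. Named genes kept their side of it in 7747, fell short in 1012 and newly passed in 178. No called list or called gene reversed its direction. A gene without a call in the main fit that changed direction was counted as keeping its side, so reversals of such genes were not counted. Against vehicle females the immune fibroblast list (median 0.82, adjusted p = 0.00123) and collagen and matrix list (0.38, 0.0132), called lower against vehicle males, were called higher by camera with the preset correlation. With an estimated correlation neither passed (adjusted p = 0.338 and 0.347). Unless stated, the cause was not tested. Numbers of genes are given against 669 (immune), 2 (fibroblast) and 159 (keratinocyte) for PTX, 43, 2 and 1 for females against males, and 381, 936 and 408 for the differences. RLE scaling gave 1 gene for PTX in fibroblasts, and moved the median log2 fold of all genes from 0.076 to 0.235 there, from -0.118 to -0.22 for immune minus fibroblast, from -0.353 to -0.195 for immune minus keratinocyte and from -0.209 to -0.079 for fibroblast minus keratinocyte. No filter gave 407 (immune PTX), 4 (fibroblast PTX) and 3 (keratinocyte sex). DESeq2 gave 2243, 640 and 1732 for PTX, 455, 219 and 710 for sex and 1887, 3216 and 2185 for the differences, and it also called unchanged genes in simulated data. Voom quality weights gave 38 (37 higher, 1 lower), 0 and 385 for PTX and 444, 8 and 5 for sex; the 0 stood beside 876 fibroblast genes at an unadjusted p under 0.05 by edgeR. Its precision weights ran from 0.013 to 678 in immune cells, 0.0203 to 5.05e+08 in fibroblasts and 0.0312 to 2.08e+12 in keratinocytes. Only the 2 groups compared gave 1 (fibroblast PTX), 166 (immune sex) and 1 (fibroblast sex). Pooled vehicles gave 1 (fibroblast) and 353 (keratinocyte). PTX males against vehicle females gave 213 in immune cells (28 higher, 185 lower), and genes of the own population, fewer by construction, gave 217, 8 and 21. Lists called with an estimated correlation were 0 of 32 (immune), 0 of 6 (fibroblast) and 16 of 26 (keratinocyte); fry called 1 in fibroblasts, and only the 2 groups compared gave 2 there. At a threshold of 0.01 the overlap of immune cells and keratinocytes fell from 10 to 2 for genes higher and from 5 to 0 for genes lower. In plain CPM, Ptprc in PTX keratinocytes was 188.4 and Col1a2 in vehicle female fibroblasts 8982.

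The replicate numbers showed no clear pairing of the libraries: 22 pairs had correlations of -0.0532 to 0.0994, 0 of them over 0.1, and in 9 of them the library correlated best with its own number. In libraries this variable, weak correlations cannot exclude a pairing by mouse, sort or batch, which the labels do not give. With the number as a block 148 genes were called for immune PTX, 24 for immune sex, 1 for fibroblast sex and 225 for immune minus fibroblast, and 2 lists for fibroblast PTX.

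Leaving out single libraries gave 230 (vehicle male 2) to 954 (PTX male 3) genes for PTX in immune cells, with 232 without vehicle male 3 and 279 without vehicle male 4, 0 to 4 in fibroblasts and 84 to 148 in keratinocytes, 12 to 29, 1 to 2 and 1 to 3 for sex, and 280 to 478, 672 to 1125 and 296 to 420 for the differences. Lists ranged from 27 to 32, from 1 to 6 and from 24 to 30. The fit has fewer samples there. Depth limits low genes in keratinocyte vehicle female 2, where 1 CPM is about 1 count (988712 counts in all). Without it 148 genes were called for PTX in keratinocytes, and what depth does to low genes elsewhere was not tested.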

Other observations

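The genes below were named only after their values were seen, and their p-values come from the PTX comparisons of the report. In immune libraries of males the Y-linked demethylase gene Kdm5d was at 0.0203 ± 0.0406 CPM with PTX and 15.1 ± 6.05 with vehicle (adjusted p = 0.0206 by the edgeR test, and 0.0525 without vehicle male 3). The other Y-linked genes did not pass: Eif2s3y was at 119.6 ± 44.1 against 69.9 ± 28.2 CPM (adjusted p = 0.573), Ddx3y at 87.1 ± 62.5 against 91.9 ± 33.9 (adjusted p = 0.986) and Uty at 6.06 ± 10.7 against 12.01 ± 7.19 (adjusted p = 0.894). In fibroblasts Kdm5d was at 47.3 ± 54.6 against 20.1 ± 23.04 CPM and in keratinocytes at 18.2 ± 25.1 against 52.4 ± 67.3 CPM (n = 3), with adjusted p = 0.995 and 0.971.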
